A study of Mus musculus with 2 samples.

How the data were processed

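The series holds 2 RNA-seq libraries of mouse dendritic cells grown from the bone marrow of C57BL/6 animals, 1 labelled immature and 1 labelled mature. Per the labels' protocols, marrow cells were cultured for 6 days in RPMI-1640 medium with GM-CSF at 10 ng/ml and IL-4 at 1 ng/ml, a pair of growth factors that drive precursors towards a dendritic cell fate. The protocol adds lipopolysaccharide (LPS, the bacterial cell wall component sensed through Tlr4) at 100 ng/ml for 24 h to the cells it calls sample 2, which is read here as the mature library. It does not say whether the immature cells were kept in culture for the same extra time. Both were sorted by flow cytometry on CD86 and the MHC class II molecule I-Ab; the gates are not given. RNA was taken with Trizol and a column kit and made into libraries by the standard Illumina procedure, per the labels' protocols.

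Each deposited file lists genes by Entrez Gene number, with the count of uniquely placed reads, the length of the gene model, the percent of that length covered by reads, and RPKM. The read counts are unnormalised, per the file headers, and RPKM was made by the authors from them: reads, divided by kilobases of the gene model and by each 1000000 reads counted to genes. This formula was checked and returned every deposited RPKM value within a relative deviation of 1.07e-07. The counts sum to 7.56 M reads in the immature and 8.07 M in the mature library, which equal the totals in the headers, so the listed genes hold every counted read. Only genes with at least 1 read are listed, and a gene absent from 1 file was taken as 0 reads there. The build mm8 is named in the submitters' processing notes; the aligner, the counting tool, the strandedness and the gene annotation are not given in the sources used here. Because only uniquely placed reads were counted, genes with near-identical copies elsewhere in the genome can lose reads: Gapdh, which has many processed pseudogenes, had reads over 4.31% of its length. The deposited coverage percent was used only in checks, of such losses and of the reads. For 32 genes the length differs between the files; none of them has more than 20 reads in all.

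Gene symbols were taken from the RefSeq gene table of assembly GRCm38.p6 by Entrez number or transcript accession, for 16220 of the 18090 IDs in either file. The IDs without a symbol held 0.538% of the immature and 0.758% of the mature reads. No coordinates are given, because that assembly is not the build of the files.

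With 1 library per group there is no replicate error, so no test between the groups was made and no p-value is given. Fold changes were computed as log2 of (mature RPKM + 1) over (immature RPKM + 1), a scale that understates the change of low genes, for the 11547 genes with at least 1 RPKM in at least 1 library. A gene was counted as higher or lower when it differed at least 2-fold on this scale. For single genes the plain RPKM ratio is printed with its exact 95% interval (Clopper-Pearson on the share of the gene's reads that fell in each library). These intervals cover counting error only, and reads without molecular identifiers are not independent molecules, so they are the narrowest error that applies. A gene with 0 reads was set to 3 reads for a lower bound of its fold. Shares of reads carry Wilson 95% intervals.

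A set of 32 gene lists covered presentation, signalling, metabolism, markers of other cell types of the marrow, and signs of RNA quality. The lists, the naming rule and the settings described below as set in advance were fixed before the data were examined. Each list was described by the median log2 fold of their members with at least 1 RPKM, with an exact binomial interval of the median over members. That interval takes members as independent, though genes of 1 list can vary together. It leaves out the error between libraries, so it is no test of a difference between the states. Each median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and in a second run on expression and gene length in 10 bins each. The percentile describes these libraries and is not a test. The genes named followed a rule: the 10 highest and the 10 lowest log2 folds among genes with a symbol and at least 10 RPKM in a library; from each list up to 4 members at least 2-fold higher and up to 4 at least 2-fold lower, by size; 17 genes named in advance; and the 3 most abundant genes of each of the 8 lists of other cell types. The rule gave 181 genes, of which a part is reported here. Other genes are marked as chosen after their values were seen.

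The steps were tested on simulated data. In libraries drawn from the real genes with counting noise alone, 47 of 11343 genes with at least 1 RPKM differed at least 2-fold. Of 200 genes changed 3-fold, 93.5% were called, of 200 changed 8-fold 99.5%, and of 200 changed 1.5-fold 0%. The changed genes were drawn from those with at least 2 RPKM in the mean of the libraries, so these shares do not cover lower genes. Other settings set in advance were pseudocounts of 0.1 and 5 RPKM, no filter and a filter at 5 RPKM. So were a 4-fold threshold, a demand that the counting interval lie beyond 2-fold, and 3 other scalings of the libraries. The scalings set the median fold of genes with at least 5 RPKM in both to 0, or used a common sum of RPKM. That sum was taken with all genes and without the 50 most abundant genes by RPKM of each library. Removal of a trend with gene length (lowess, span 0.3) and a restriction to genes covered over at least 50% of their length were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.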

Results

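RNA of mouse dendritic cells (DC), the cells that take up antigen in tissues and present it to T cells in lymph nodes, was sequenced in 2 libraries: 1 of immature DC and 1 of mature DC. Both came from bone marrow of the C57BL/6 strain cultured with GM-CSF and IL-4 and sorted on surface CD86 and I-Ab, and the mature cells had received lipopolysaccharide (LPS) for 24 h. The immature library held 7.56 M reads counted to 16573 genes and the mature library 8.07 M reads counted to 16646 genes, with a median of 82 reads per listed gene in each. A gene of 1000 bases with 3 reads stood at 0.397 RPKM (reads per kilobase of gene and per 1000000 reads) in the immature and 0.372 RPKM in the mature library. There was no replicate of either state, so each difference below is a difference between these 2 libraries and no test was made. Ratios are of mature to immature RPKM, with the exact 95% counting interval in parentheses, which covers counting error only.

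The design asks how the transcriptome differed between immature and mature cells. In the mature library, at least 2-fold higher values were found for 14 of 20 costimulation genes and 22 of 39 interferon-stimulated genes. They were also found for 15 of 20 genes of a list for mature DC migration and cytoskeleton, which holds chemokine genes too. At least 2-fold lower values were found for 38 of 39 cell cycle genes, 15 of 21 neutrophil and granulocyte precursor genes and 11 of 21 macrophage and monocyte genes. In smaller part, 10 of 23 MHC class I genes and 9 of 20 cytokine genes were higher, and 17 of 36 uptake receptors and 10 of 26 cholesterol genes were lower. Among 11547 genes with at least 1 RPKM in a library, 1045 (9.05%) were at least 2-fold higher in the mature library, 1310 (11.3%) at least 2-fold lower, and 9192 lay within 2-fold. With a pseudocount of 5 RPKM the numbers were 469 higher and 686 lower. At 4-fold they were 197 and 316, and the counting interval lay wholly beyond 2-fold for 794 and 973 genes. After either rescaling to a common sum of RPKM the order of the directions turned, with 1198 genes higher against 1174 lower, and 1221 against 1155 when the 50 most abundant genes were left out of the sum.

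The 10 genes with the highest log2 fold among those reaching 10 RPKM included Ccl5 (Entrez Gene 20304), a chemokine for T cells and monocytes, at 109 and 7849 RPKM, 72.1-fold higher (65.8 to 79) in the mature library. Nos2 (18126), the inducible nitric oxide synthase, was 26.9-fold higher (24.1 to 30.1), Stat4 (20849), a signal transducer of the interleukin-12 receptor, 21.3-fold higher (18.4 to 24.8), and Cd200 (17470), a surface ligand of an inhibitory receptor on myeloid cells, 32.8-fold higher (22.5 to 49.6). Also among the 10 were the semaphorin gene Sema7a, 23.9-fold higher (20.3 to 28.3), the acute phase gene Saa3, 23.3-fold higher (17.4 to 31.9), Ceacam15, 33.8-fold higher (23.2 to 51.1), and Igfbp4, which encodes a binding protein of insulin-like growth factors, 18.7-fold higher (17.2 to 20.4). Enpp2, which encodes the enzyme autotaxin, and Il12b, which encodes the p40 subunit of interleukin-12, rested on 2 immature reads each against 1005 and 369 mature reads, ratios of 471-fold (130.0 to 3893) and 173-fold (47.5 to 1433). The 10 lowest genes included Asgr2 (11890), a subunit of the asialoglycoprotein receptor, at 147 and 0.992 RPKM, 148-fold lower (82.4 to 297). They further held the cell cycle genes Rrm2, Ube2c and Ccna2 and the granulocyte genes Prg2 and Ear2. Cdca3, a gene of mitotic entry, was 77.1-fold lower (42.9 to 155), Retnla 33.4-fold lower (21.2 to 55.9), Ifitm6 35.1-fold lower (21.1 to 63.2) and Rnase6, on 2 mature reads, 137-fold lower (37.6 to 1139).

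**Figure D1:**
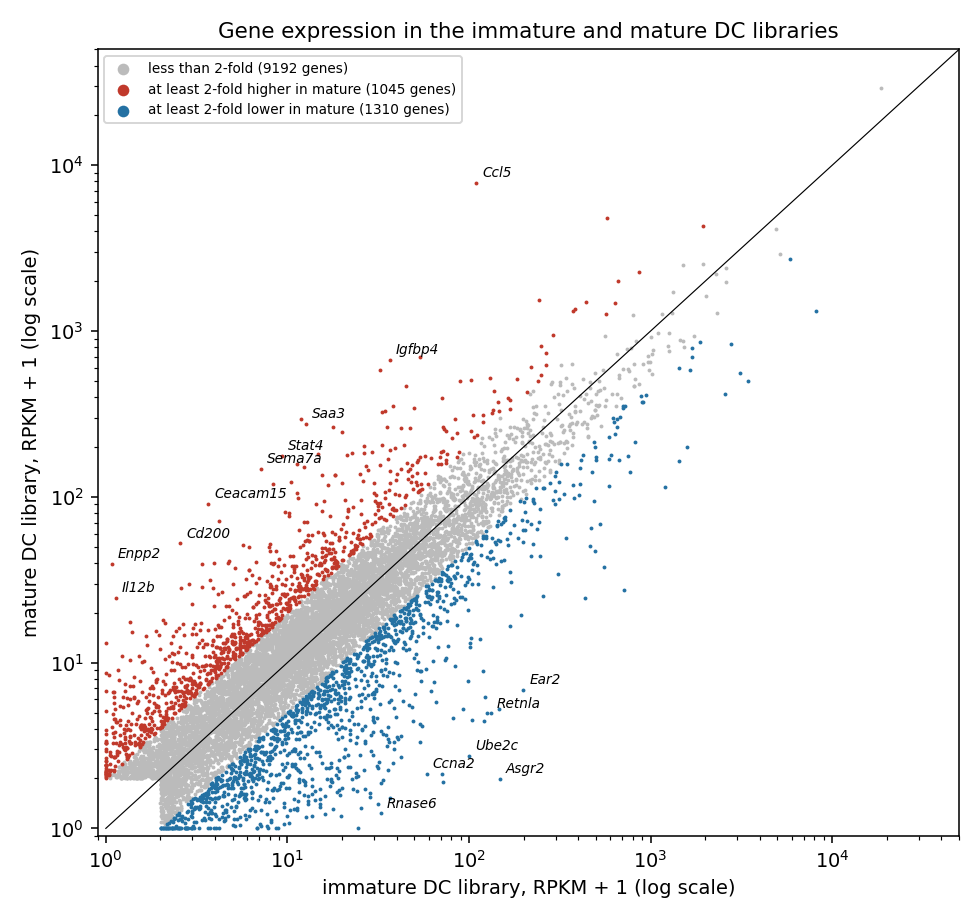
Each point is 1 of 11547 genes, placed by RPKM + 1 in the immature library (horizontal, log scale) and in the mature library (vertical, log scale), with part of the 20 genes of highest and lowest fold labelled. Red points (1045 genes) were at least 2-fold higher and blue points (1310 genes) at least 2-fold lower in the mature library, the black line marks equal values, and Ccl5 stands apart at 7849 RPKM in the mature library.

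The genes of the surface markers used for the sort check the labels and are no finding. Cd86 stood at 26.1 and 152 RPKM in the immature and mature libraries, 5.82-fold higher (5.29 to 6.4). The genes of the MHC class II chains were abundant in both libraries and differed little: H2-Ab1 stood at 1256 and 978 RPKM, H2-Aa at 1159 and 1260.4 RPKM and H2-Eb1 at 655 and 732 RPKM.

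Of 20 compared genes for costimulation and maturation of the cell surface, 14 were at least 2-fold higher in the mature library, 1 was lower and 5 lay within 2-fold. The list's median log2 fold was 2.43 (95% interval over members 0.91 to 2.80), at percentile 100 of random lists of matched expression. The sort on CD86, whose gates are not given, may bear on this list, which was not tested. Cd80, a ligand of CD28 on T cells, was 7.21-fold higher (6.42 to 8.11), Cd40, the receptor of the T cell ligand CD40L, 6.08-fold higher (4.75 to 7.89), and Cd83, a marker of mature DC, 8.83-fold higher (7.88 to 9.92). Slamf1, a homophilic receptor of leukocytes, was 13.2-fold higher (10.1 to 17.4), and Il15ra, which presents interleukin-15, 10.6-fold higher (7.68 to 14.9). Icosl, the ligand of the T cell receptor ICOS, went the other way and was 4.43-fold lower (3.5 to 5.66). Of 20 genes for migration and the cytoskeleton of mature DC, 15 were higher, 1 was lower and 4 lay within 2-fold. The median was 1.57 (1.17 to 2.82) at percentile 100. Of these genes, 9 stand in another list too. Ccr7, the receptor that guides DC to lymph nodes, was 18.4-fold higher (16.8 to 20.2), and Cacnb3, a calcium channel subunit, 15.7-fold higher (14.1 to 17.5). The lower member was Ccl17, a chemokine for T cells, 3.31-fold lower (3.18 to 3.43). Outside both lists, Itgax, which encodes the DC integrin CD11c, was 2.75-fold lower (2.66 to 2.84).

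Among MHC class I presentation genes, 10 of 23 were higher, 0 were lower and 13 lay within 2-fold. The median was 0.72 (0.14 to 1.34) at percentile 100. The heavy chain genes H2-K1 and H2-D1 were 3.38-fold higher (3.28 to 3.48) and 3.57-fold higher (3.46 to 3.68), and B2m, the light chain, 2.22-fold higher (2.18 to 2.27). H2-Q7 was 9.09-fold higher (7.31 to 11.4) and H2-T22 4.94-fold higher (3.81 to 6.49). Both share sequence with other family members and were covered by reads over 25.1% and 40.2% of their lengths in the mature library, so their values are uncertain. The class II presentation list was centred near 0, with 1 of 18 genes higher, 2 lower and 15 within 2-fold. The median was -0.017 (-0.68 to 0.36) at percentile 68.2. Over the other settings it ranged from -0.055 to 0.074, and its sign turned under both rescalings to a common sum and with the gene length trend removed. Whether the sort on I-Ab, whose gates are not given, bears on the class II list was not tested. H2-DMa, a chain of the peptide loading chaperone, was 3.08-fold lower (2.8 to 3.38), H2-DMb2 2.22-fold lower (1.91 to 2.59), and Lgmn, a protease of antigen processing, 2.59-fold higher (2.46 to 2.73).

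Cytokine genes were higher more often than lower, 9 of 20 against 2, with 9 within 2-fold and a median of 0.75 (0.0010 to 1.52) at percentile 100. With a pseudocount of 5 RPKM, 7 cytokine genes in place of 11 were at least 2-fold apart. Il6, a pleiotropic inflammatory cytokine, was 9.22-fold higher (7.64 to 11.2), Vegfa, the endothelial growth factor, 10.6-fold higher (9.97 to 11.2), Il15, a cytokine for T and NK cells, 7.07-fold higher (4.52 to 11.6), and Il1b 2.42-fold higher (2.28 to 2.56). Tnf, an early product of LPS stimulation, was 3.41-fold lower (2.94 to 3.96), and Il16 3.26-fold lower (2.62 to 4.09). The chemokine list was split, with 5 of 19 higher, 4 lower, 10 within 2-fold and a median of 0.12 (-0.75 to 1.16) at percentile 88.7, or 96.6 when gene length was matched too. The chemokine median was 0.29 with the gene length trend removed, and 0.40 both with a filter at 5 RPKM and among genes covered over at least 50% of their length. Besides Ccl5, Ccl22, a ligand of the receptor CCR4, stood at 575 and 4791 RPKM, 8.34-fold higher (8.14 to 8.53), Cxcl16 was 7.0-fold higher (6.53 to 7.51), and Cx3cl1 5.0-fold higher (4.09 to 6.15). Besides Ccl17, which binds the same receptor as Ccl22, Ccl6 was 6.13-fold lower (5.94 to 6.32), Ccl24 3.78-fold lower (3.44 to 4.17) and Ccl9 2.28-fold lower (2.2 to 2.35). Receptors of chemokines and chemoattractants were split as well, with 5 of 16 higher and 5 lower, a median of -0.28 (-1.22 to 1.64) at percentile 13.9 and a mean of 0.024. The receptor median reached -0.19 under rescaling without the 50 most abundant genes. Besides Ccr7, Cxcr5, a receptor for homing to B cell follicles, was 26.5-fold higher (12.6 to 66.8) and Cxcr4 3.37-fold higher (2.93 to 3.89), while Ccr2, the receptor of monocyte egress from marrow, was 31.6-fold lower (26.2 to 38.4) and Cmklr1 3.16-fold lower (2.86 to 3.5).

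**Figure D2:**
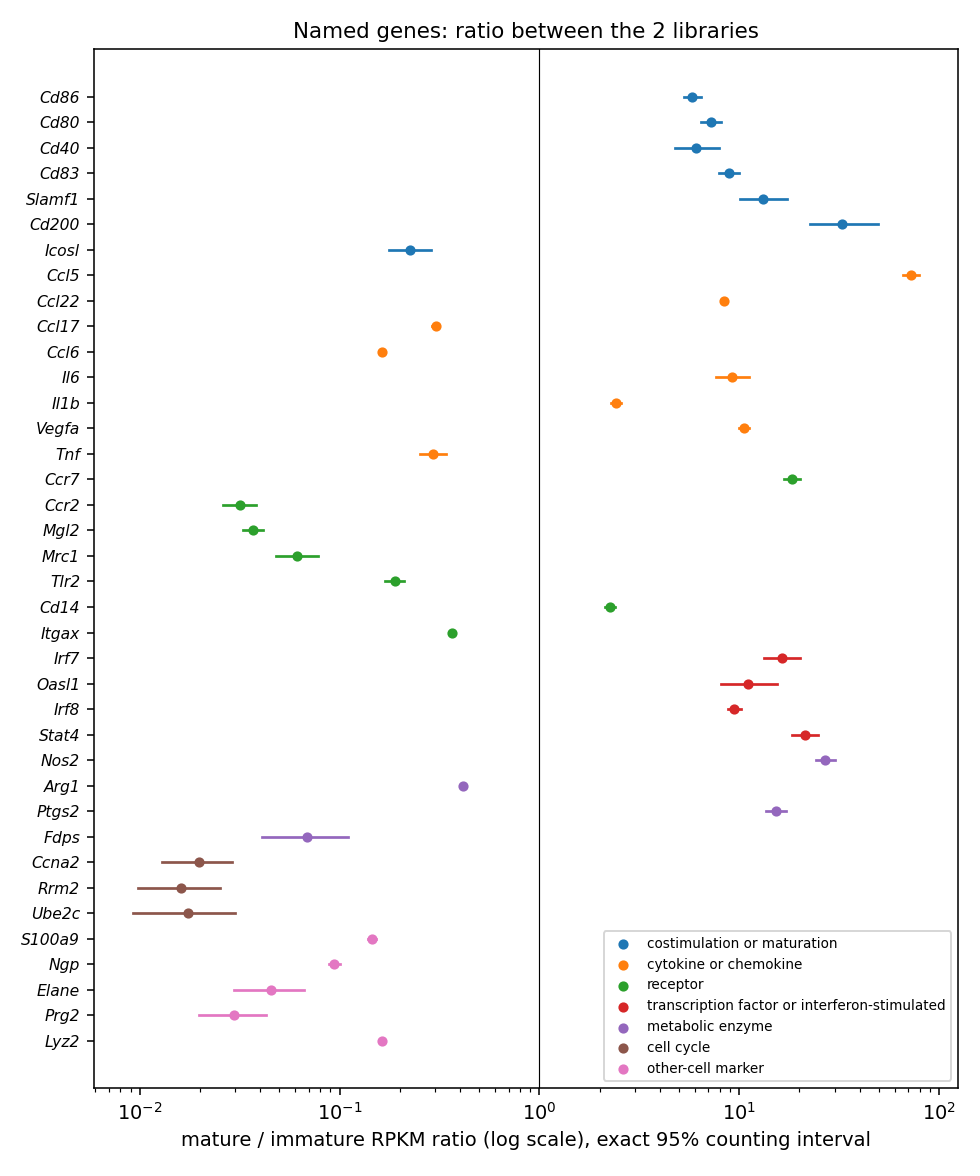
Ratio of mature to immature RPKM (horizontal, log scale) of selected genes from the naming rule, with points for the ratio, lines for the exact 95% counting interval and colours for the kind of gene. Cd86, Cd80, Cd40 and Cd83 lie between 5.82-fold and 8.83-fold higher in the mature library, while Rrm2, Ube2c and Ccna2 lie at 61.9-fold, 57.2-fold and 50.6-fold lower.

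Interferon-stimulated genes were higher in 22 of 39 cases, lower in 0 and within 2-fold in 17. The median was 1.28 (0.68 to 1.5) at percentile 100. Irf7, a transcription factor of the interferon response, was 16.3-fold higher (13.3 to 20.1), Oasl1 11.1-fold higher (8.13 to 15.4), the guanylate-binding protein gene Gbp5 7.12-fold higher (6.03 to 8.47) and Herc6 6.8-fold higher (5.88 to 7.9). In the NF-kB pathway and feedback list, 8 of 29 were higher, 0 lower and 21 within 2-fold. The median was 0.62 (0.39 to 0.99) at percentile 100. Map3k14, the kinase of the non-canonical pathway, was 10.2-fold higher (9.1 to 11.5), and the adaptor Traf1 8.02-fold higher (7.27 to 8.86). Toll-like receptor and LPS sensing genes were split, with 4 of 26 higher, 7 lower and 15 within 2-fold. The median was 0.080 (-0.83 to 0.61) at percentile 64.9 and the mean -0.086. With the gene length trend removed the median was -0.014, under rescaling without the 50 most abundant genes it was 0.16, and with a pseudocount of 5 RPKM the members at least 2-fold apart numbered 5 in place of 11. Tlr4, the LPS receptor, was 1.24-fold higher (1.14 to 1.35), its partners Ly96 and Cd14 4.74-fold higher (3.3 to 6.97) and 2.25-fold higher (2.12 to 2.38), and the adaptor Ticam1 3.9-fold higher (3.35 to 4.56). Tlr2, which senses bacterial lipoproteins, was 5.31-fold lower (4.74 to 5.95), and the inflammasome adaptor Pycard 3.7-fold lower (3.3 to 4.16). DC transcription factors were higher in 10 of 37 cases, lower in 6 and within 2-fold in 21. The median was 0.16 (-0.23 to 0.74) at percentile 90.1, and between 0.13 and 0.25 over the other settings. Irf8, a factor of DC lineages, was 9.42-fold higher (8.76 to 10.1) and Runx3 3.33-fold higher (3.11 to 3.57), while Myc, a driver of growth, was 11.3-fold lower (8.29 to 15.8) and Pparg 4.04-fold lower (3.05 to 5.4).

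Receptors for antigen uptake were lower in 17 of 36 cases, higher in 3 and within 2-fold in 16. The median was -0.90 (-1.42 to 0.13) at percentile 0. The C-type lectin genes Mgl2 and Clec12a were 27-fold lower (24.2 to 30.3) and 21.7-fold lower (17.2 to 27.7), and Mrc1, the mannose receptor, 16.3-fold lower (12.9 to 20.8). Ly75, which encodes the uptake receptor DEC-205, was 4.37-fold higher (3.96 to 4.84), Itgav 5.2-fold higher (4.67 to 5.8) and Clec4d 2.29-fold higher (2.17 to 2.43). Lysosome and endosome genes lay mostly within 2-fold, 30 of 39, with 4 higher and 5 lower and a median of 0.074 (-0.19 to 0.41) at percentile 93.2, or 0.17 under rescaling without the 50 most abundant genes. Npc2, a cholesterol carrier of lysosomes, was 3.18-fold higher (3.06 to 3.3), and the protease gene Ctsc 3.43-fold lower (3.27 to 3.59).

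Cell cycle genes were lower in the mature library almost throughout. Of 39 compared, 38 were at least 2-fold lower and 0 higher, with a median log2 fold of -3.43 (-3.70 to -2.67) at percentile 0. Rrm2, a subunit of ribonucleotide reductase, stood at 69.7 and 1.13 RPKM, 61.9-fold lower (39.9 to 102). Ube2c, the ubiquitin-conjugating enzyme of mitotic exit, was 57.2-fold lower (33.2 to 108), and the cyclin Ccna2 50.6-fold lower (34.4 to 77.8). Stmn1, a regulator of microtubules, had 190 reads in the immature and 0 in the mature library, at least 67.6-fold lower at a floor of 3 reads (54.4-fold at the wider bound of the exact interval), with reads over only 27.9% of its length in the immature library. The member within 2-fold, E2f1, a transcription factor of S phase entry named after its value was seen, was 1.45-fold lower (1.25 to 1.68). The list's median depended on the pseudocount, at -3.88 with 0.1 RPKM and -2.24 with 5 RPKM.

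Cholesterol synthesis and efflux genes were lower in 10 of 26 cases, higher in 1 and within 2-fold in 15. The median was -0.81 (-1.10 to -0.58) at percentile 0, and with a pseudocount of 5 RPKM the members at least 2-fold apart numbered 5 in place of 11. The synthesis enzymes Fdps and Cyp51 were 14.6-fold lower (9.13 to 24.6) and 4.53-fold lower (3.96 to 5.19), and Abca1, which exports cholesterol, was 5.2-fold higher (4.76 to 5.7). Genes of arginine, tryptophan and itaconate enzymes and related inflammatory enzymes were higher in 8 of 20 cases, lower in 4 and within 2-fold in 8. The median was 0.77 (-0.59 to 1.25) at percentile 100, but the median was 0.42 with a pseudocount of 5 RPKM and 0.47 with a filter at 5 RPKM. Besides Nos2, Ptgs2, the inducible prostaglandin synthase, was 15.2-fold higher (13.6 to 17.1), and the haem oxygenase gene Hmox1 3.53-fold higher (3.42 to 3.65). Arg1, an arginase that shares the substrate of Nos2, was 2.42-fold lower (2.35 to 2.48), and Kmo, of tryptophan breakdown, 16.1-fold lower (11.8 to 22.5). Oxidative phosphorylation genes were slightly lower as a group, with 5 of 40 at least 2-fold lower, 1 higher, 34 within 2-fold and a median of -0.64 (-0.79 to -0.49) at percentile 0.01, or 0.33 when gene length was matched too. Members at least 2-fold apart numbered 2 with a pseudocount of 5 RPKM and 3 among genes covered over at least 50% of their length, in place of 6. The complex I genes Ndufb8 and Ndufs8 were 2.84-fold lower (2.44 to 3.32) and 2.83-fold lower (2.34 to 3.45), and Cox7c, a short gene with 11 and 31 reads, was 2.64-fold higher (1.29 to 5.82). Glycolysis and glucose uptake genes were mostly within 2-fold, 23 of 28, with 2 higher, 3 lower and a median of -0.21 (-0.44 to 0.063) at percentile 29.8, and between -0.28 and -0.11 over the other settings. With a pseudocount of 5 RPKM, 3 glycolysis genes in place of 5 were at least 2-fold apart. Pfkfb3, an activator of glycolysis, was 8.53-fold higher (7.66 to 9.54), and the transporter gene Slc2a6 3.06-fold lower (2.78 to 3.38).

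**Figure D3:**
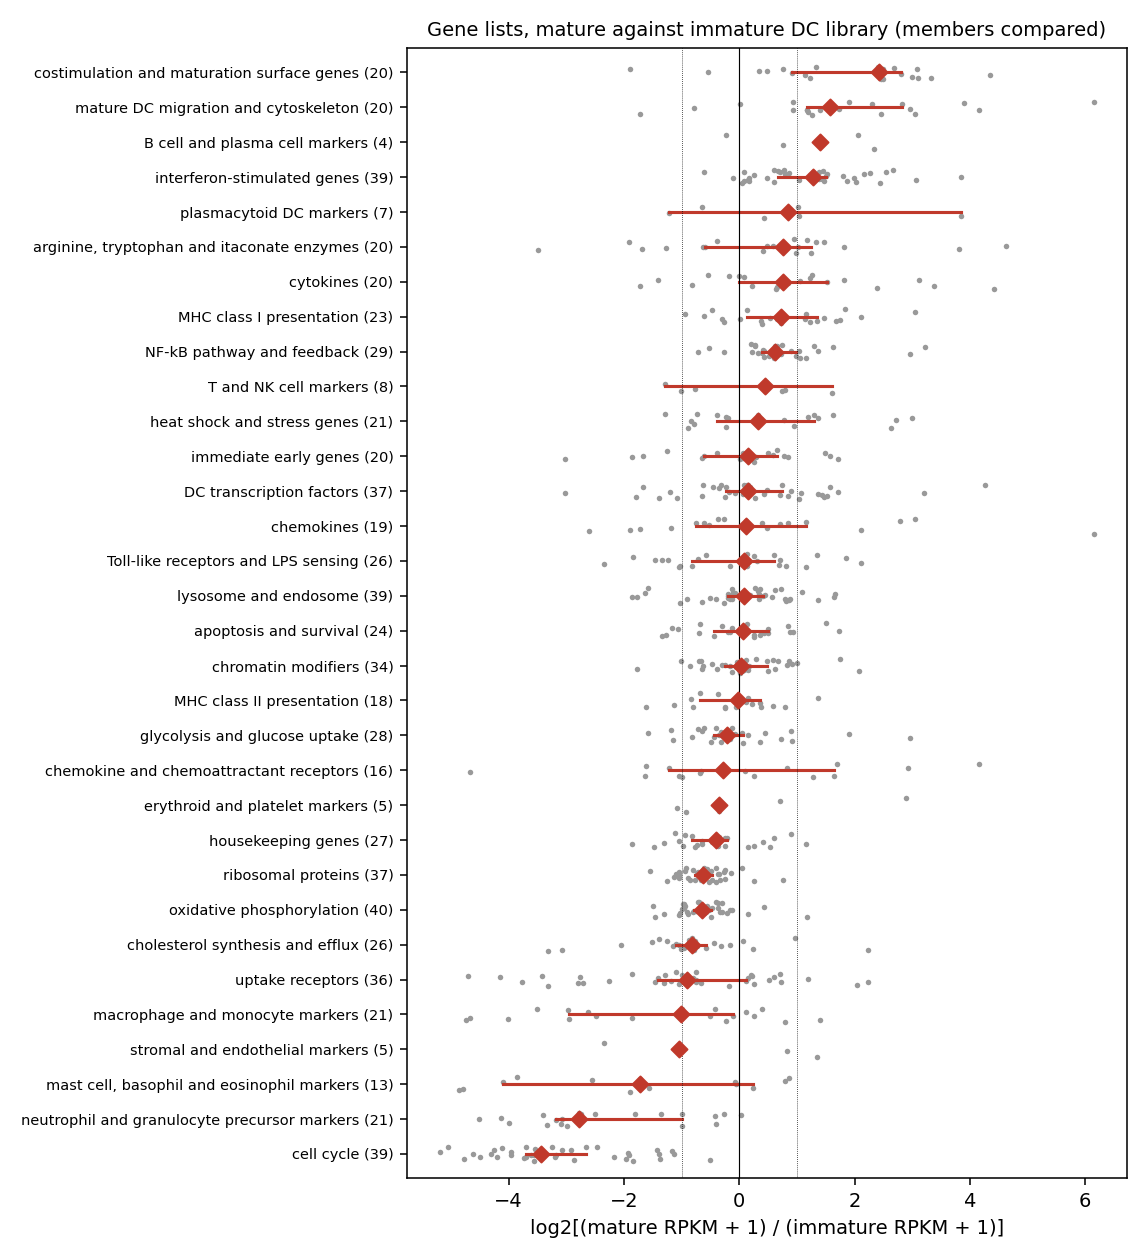
Log2 of (mature RPKM + 1) over (immature RPKM + 1), horizontal, for members of 32 gene lists (grey points, number of compared members in parentheses), with the list median as a red diamond and its exact binomial 95% interval as a red line for lists of at least 6 members. The median lies at 2.43 for costimulation genes and at -3.43 for cell cycle genes, and dotted lines mark 2-fold.

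Markers of other cells of the marrow were measured because a sort on CD86 and I-Ab could leave such cells in. Neutrophil and granulocyte precursor genes were lower in 15 of 21 cases, higher in 0 and within 2-fold in 6. The median was -2.78 (-3.17 to -0.996) at percentile 0. Elane and Mpo, enzymes of primary granules, were 22.1-fold lower (15 to 33.8) and 27.8-fold lower (18.8 to 42.9), and Camp and Ngp, of later granules, 29.2-fold lower (18 to 50.6) and 10.6-fold lower (9.99 to 11.3). The abundant calcium-binding protein genes S100a9 and S100a8 stood at 3449 and 501 RPKM and 1587 and 199 RPKM. Mast cell, basophil and eosinophil genes were lower in 8 of 13 cases, or 5 with a pseudocount of 5 RPKM, and higher in 0. The median was -1.72 (-4.09 to 0.24) at percentile 0, and depended on the settings, at -0.36 with no filter, -3.2 with a filter at 5 RPKM, -0.69 with a pseudocount of 5 RPKM and -2.89 with one of 0.1 RPKM. The eosinophil granule genes Prg2 and Epx were 33.8-fold lower (23.3 to 50.7) and 33.6-fold lower (21.8 to 54.7), and Ear2 33.7-fold lower (24 to 49), the last with a near-identical paralogue, Ear1. Macrophage and monocyte genes, which DC share in part and of which 6 stand in another list, were lower in 11 of 21 cases and higher in 1. The median was -1.02 (-2.95 to -0.10) at percentile 0. Lyz2, the lysozyme gene of myeloid cells with a close paralogue, Lyz1, stood at 8168 and 1324 RPKM, 6.17-fold lower (6.05 to 6.29), the complement gene C1qb was 22.7-fold lower (14.5 to 37.6), and Gpnmb, at 863 and 2282 RPKM, was 2.64-fold higher (2.6 to 2.68). A median below 0 was not particular to these groups. Those of the cell cycle (-3.43), uptake (-0.90), cholesterol (-0.81), oxidative phosphorylation (-0.64), ribosomal protein (-0.62) and housekeeping (-0.41) lists lay below 0 too. Of these, only the cell cycle median was as low as those of the neutrophil and mast cell lists.

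The remaining marker lists held few expressed members. T and NK cell genes were higher in 1 of 8 cases and lower in 2, with a median of 0.45 (-1.29 to 1.62) at percentile 88.9. The number at least 2-fold apart was 6 with a pseudocount of 0.1 RPKM and 1 with one of 5 RPKM. Over the other settings the median ranged from 0.12 with no filter to 0.73 with a pseudocount of 0.1 RPKM. The granzyme gene Gzmb was 4.03-fold higher (2.54 to 6.65) and Thy1 2.5-fold lower (2.23 to 2.81). B cell and plasma cell genes were higher in 2 of 4 cases, with a median of 1.4 at percentile 99.8, but a median of 0.034 with no filter. Sdc1, a heparan sulfate proteoglycan, was 5.14-fold higher (4.79 to 5.53) and the adaptor Blnk 4.38-fold higher (3.78 to 5.1). Plasmacytoid DC genes, of which Irf7 and Bst2 are interferon-stimulated too, were higher in 3 of 7 cases and lower in 1. The median was 0.85 (-1.22 to 3.85) at percentile 99.1. The number at least 2-fold apart was 2 in place of 4 with a pseudocount of 5 RPKM and with the gene length trend removed, and the median was 0.42 with a pseudocount of 5 RPKM and 0.15 with no filter. Erythroid and platelet genes were higher in 1 of 5 cases and lower in 1, and 1 was at least 2-fold apart with a pseudocount or a filter of 5 RPKM. The median was -0.36 at percentile 22.2, the mean was 0.25, and the median was 0.70 with a filter at 5 RPKM, 0.17 among genes covered over at least 50% of their length and -0.10 with no filter. Car2, a carbonic anhydrase, was 7.83-fold higher (6.84 to 9.01). Stromal and endothelial genes were lower in 3 of 5 cases and higher in 1, but the number at least 2-fold apart was 2 under both rescalings to a common sum and 1 with a pseudocount of 5 RPKM. The median was -1.04 at percentile 1.37, but the median was -0.63 with a pseudocount of 5 RPKM and -0.092 with no filter. Fn1, fibronectin, was 5.12-fold lower (4.99 to 5.25). For the lists of 4 and 5 members no interval of the median was formed.

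Survival and chromatin genes lay mostly within 2-fold. In the apoptosis and survival list 2 of 24 were higher, 4 lower and 18 within 2-fold. The median was 0.070 (-0.43 to 0.49) at percentile 72.3, or 0.16 under rescaling without the 50 most abundant genes and 0.25 among genes covered over at least 50% of their length, where 3 members in place of 6 were at least 2-fold apart, as with a pseudocount of 5 RPKM. Cflar, an inhibitor of death receptor signals, was 2.97-fold higher (2.74 to 3.21), and Bcl2, which guards mitochondria, 4.02-fold lower (3.01 to 5.44). Bcl2a1a, Bcl2a1c and Bcl2a1d were lower too but are near-identical copies. Of 34 chromatin modifiers 3 were higher, 2 lower and 29 within 2-fold, while 8 were at least 2-fold apart with a pseudocount of 0.1 RPKM and 2 with one of 5 RPKM. The median was 0.027 (-0.26 to 0.49) at percentile 44.3, or -0.078 with the gene length trend removed and 0.14 under rescaling without the 50 most abundant genes. The histone methyltransferase gene Ezh1 was 4.52-fold higher (4.03 to 5.08) and the DNA methyltransferase gene Dnmt3a 3.87-fold lower (3.46 to 4.33).

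Lists for RNA quality and handling were measured beside these groups. Ribosomal protein genes were lower in 7 of 37 cases, higher in 0 and within 2-fold in 30. The number at least 2-fold apart was 4 under both rescalings to a common sum, and 2 with the gene length trend removed, among genes covered over at least 50% of their length, and with a pseudocount of 5 RPKM. The median was -0.62 (-0.76 to -0.48) at percentile 0.01, or 1.96 when gene length was matched too. The median was -0.30 with the gene length trend removed. Heat shock and stress genes were higher in 7 of 21 cases and lower in 1. The median was 0.33 (-0.39 to 1.30) at percentile 97.4. The largest ratios of this list were those of the inducible chaperone genes Hspa1b, with 1 and 168 reads, 157-fold higher (27.9 to 6253), and Hspa1a, with 4 and 155 reads, 36.3-fold higher (13.9 to 135). These are near-identical copies, so their values are uncertain. The chaperone gene Hsph1 was 3.15-fold higher (2.92 to 3.4), Ddit4, an inhibitor of mTORC1, 10.1-fold higher (6.16 to 17.8), and the endoplasmic reticulum chaperone gene Hsp90b1 2.46-fold lower (2.39 to 2.52). Immediate early genes were higher in 3 of 20 cases and lower in 4, with a median of 0.16 (-0.62 to 0.65) at percentile 84.4 and a mean of -0.032. This median was 0.29 both with a filter at 5 RPKM and among genes covered over at least 50% of their length. Fos was 3.4-fold higher (2.97 to 3.9) and Egr2 3.24-fold lower (2.98 to 3.53). Housekeeping genes were lower in 5 of 27 cases and higher in 1. The median was -0.41 (-0.83 to -0.22) at percentile 4.15, or 9.76 when gene length was matched too. Of these housekeeping genes, 8 stand in another list. Actb, beta-actin, stood at 5872 and 2704 RPKM, 2.17-fold lower (2.15 to 2.2), and Gapdh, of which reads covered 4.31% of the length, at 17.3 and 19.4 RPKM, a ratio of 1.12-fold (0.905 to 1.39).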

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

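The tests in this part were chosen only after the results they bear on were seen, except that the scaling without the 50 most abundant genes was set in advance, though not what it would have to show.

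The percent of gene length covered by reads was set against the read counts, since a like number of reads should cover a like share of a gene. Among 7182 genes with at least 100 reads in each library, coverage differed by over 15 percentage points against the direction of the reads in 4, all chosen after their values were seen. Mature minus immature, the difference was -20.4 points for Ankrd10 (190 and 204 reads), -18.04 for Fam122a (129 and 142 reads), -16.77 for Exosc1 (139 and 166 reads) and 15.03 for Mtus1 (655 and 420 reads). No control library was there for comparison.

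Cell cycle genes were at least 2-fold lower in 38 of 39 cases in the mature library. A trend of fold with gene length was too small to account for it, as medians over 10 classes of length lay between -0.35 and 0.26. Removing that trend could therefore hardly have moved the cell cycle median far, and the median was -3.39 (-3.81 to -2.78) afterwards. Counting error did not account for the pattern either, since for 37 of 39 members the counting interval lay wholly beyond 2-fold lower. Less division after LPS is a candidate explanation on the side of biology, untested here. A sort that kept fewer dividing cells of another type may contribute as well. So may time in culture, since the protocol does not say whether the immature cells were kept for the same extra time. With 1 library per state these cannot be separated.

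In the mature library 15 of 21 neutrophil, 8 of 13 mast cell, basophil and eosinophil and 11 of 21 macrophage and monocyte genes were at least 2-fold lower, and for 14 of 21 neutrophil list members the counting interval lay wholly beyond 2-fold lower, more than counting error gives. A candidate explanation is that fewer granulocyte precursors passed the sort on CD86 and I-Ab: Elane, Mpo, Prtn3, Ctsg, Camp, Ngp, Ltf and Cebpe were a median of 15.6-fold lower (7.25 to 29.2 over the genes), but they were chosen for the pattern, so the test leaves this open. Whether granulocytes of every stage were fewer is open too: Mmp8, Mmp9, Lcn2 and Csf3r were a median of 1.27-fold lower, but they were picked as list members within 2-fold, so that value decides nothing, and S100a9 and S100a8 were 6.89-fold lower (6.57 to 7.23) and 7.96-fold lower (7.32 to 8.66). S100a9 stood at 3449 and Ngp at 1204 RPKM in the immature library, and a change of transcription within DC on maturation, untested, stays open beside a change in the mix of cells. A difference in time in culture between the libraries, which the protocol does not exclude, cannot be told apart from either.

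The median log2 folds of ribosomal protein and oxidative phosphorylation genes lay below 0, though most members were within 2-fold (30 of 37 and 34 of 40), and the median of short genes lay below 0 too: over 8020 genes of at least 5 RPKM on average, Spearman's rho between gene length and log2 fold was 0.20 across genes, which are not independent, with a median of -0.35 in the shortest of 10 length classes (77 to 1070 bases) and 0.26 in the longest (5747 to 19805 bases). With a length trend fitted over the 11547 compared genes removed, the ribosomal protein median was -0.30 (-0.56 to -0.20), against -0.62 before. For oxidative phosphorylation it was -0.44 (-0.60 to -0.26), against -0.64 before. The central 95% of random lists matched on expression and length had medians of -0.61 to -0.063 and -0.54 to -0.037. Length may account for a part. Whether it accounts for all stays open, because the intervals take the members of a list as independent. The 15 ribosomal members covered over at least 50% of their length in both libraries had a median of -0.56 (-0.71 to -0.25). This value cannot decide whether reads lost to near-identical copies played a part. Unique placement was required in both libraries, and coverage of that extent does not show a member free of such losses. A few abundant genes taking reads did not account for the ribosomal proteins. Their median was -0.52 (-0.67 to -0.38) when the 50 most abundant genes of each library were left out of the scaling. That scaling shifted all log2 folds by 0.099, and the common sum with all genes kept by 0.086. The 50 genes with most reads held 17.7% of immature and 17.1% of mature reads. No biological explanation was tested.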

How the results depend on the processing

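Removal of the gene length trend and the restriction to genes covered over at least 50% of their length were chosen after the data were seen; the other alternatives were planned. No list median whose interval excluded 0 turned its direction. Medians close to 0 or of short lists (class II presentation, Toll-like receptors, chromatin and erythroid genes) changed sign under some settings. The 181 named genes kept their sign in all 1603 values under the alternatives, but this was nearly fixed in advance. A pseudocount, a filter or the coverage restriction cannot turn the sign of a gene's fold. The other scalings shifted log2 folds by only -0.017, 0.086 and 0.099. Most named genes were chosen for a change of at least 2-fold, so their kept signs say little about robustness. Of the list medians, 283 values stayed within the interval or spread of the list and 5 moved. For lists with wide intervals this says little about robustness. The mast cell, basophil and eosinophil median of -1.72 counted as stayed at -0.36 with no filter and at -3.2 with a filter at 5 RPKM. Its interval was -4.09 to 0.24. Lists without an interval were judged by the spread of their members, which is wide too. Of the member counts, 263 stayed within 1.5 times and 25 moved, and of the gene counts 18 and 4. Of the log2 folds of named genes, 1359 values stayed within the counting interval and 244 moved, of which 102 with a pseudocount of 5 RPKM and 29 with one of 0.1 RPKM, 48 with the length trend removed, and 31 and 34 under the rescalings to a common sum. No filter at all changed no gene count, since a gene under 1 RPKM in both libraries cannot reach 2-fold with a pseudocount of 1. The cause of the changes below was not tested unless stated.

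With a pseudocount of 5 RPKM, which shrinks low genes by construction, 469 genes were higher and 686 lower, the cell cycle median was -2.24, and the members at least 2-fold apart numbered 7 for cytokines, 5 for Toll-like receptors, for cholesterol and for mast cells and eosinophils, 3 for glycolysis and for apoptosis, 2 for oxidative phosphorylation, ribosomal proteins, chromatin and plasmacytoid DC, and 1 for T and NK, erythroid and stromal cells. With a pseudocount of 0.1 RPKM the cell cycle median was -3.88, and members numbered 6 for T and NK cells and 8 for chromatin. At a threshold of 4-fold, stricter by construction, 197 genes were higher and 316 lower. With no filter the B cell median was 0.034, as genes near 0 entered, and with a filter at 5 RPKM the erythroid list had 1 such member. Under both rescalings to a sum of 1000000, with and without the 50 most abundant genes, stromal members numbered 2 and ribosomal members 4. With the length trend removed, the median was -0.30 for ribosomal proteins and -0.44 for oxidative phosphorylation, and members numbered 2 for ribosomal proteins and 2 for plasmacytoid DC. Among genes covered over at least 50%, members numbered 3 for apoptosis, 3 for oxidative phosphorylation and 2 for ribosomal proteins, fewer in part because fewer genes were compared. No paired analysis was possible because each state has 1 library. Depth limited low genes most: ratios resting on 2 reads, as for Il12b, have intervals that span more than 10-fold.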

Other observations

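A few genes of iron handling, not a fixed list, were picked after their values were seen, apart from Tfrc, the transferrin receptor of iron uptake, which the naming rule gave and which was 1.29-fold lower (1.19 to 1.39). Fth1, the ferritin heavy chain, was the most abundant transcript of both libraries, with 1.61% of immature reads (Wilson 95% interval 1.6 to 1.61) and 2.53% of mature reads (2.52 to 2.54), 1.58-fold higher (1.56 to 1.59) by RPKM. Ftl1, the ferritin light chain, was 1.31-fold higher (1.29 to 1.34), with reads over 37.6% of its length in the immature library, so its value is uncertain. Hamp, the hormone hepcidin that closes the iron exporter, had 10 immature and 234 mature reads and was 21.9-fold higher (11.7 to 46.3), while Slc40a1, the exporter itself, was 1.91-fold higher (1.53 to 2.4).

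Among 47 gene IDs without a symbol that reached 10 RPKM in a library, 8 were at least 2-fold higher and 4 at least 2-fold lower in the mature library.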
